A study of Arabidopsis thaliana with 48 samples.

How the data were processed

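Messenger RNA of rosette leaves was sequenced in 48 libraries, 3 for each of 16 groups of genotype (Col or myb30), leaf (local or systemic) and minutes of high light (0, 2, 8 or 30). The labels state pools of at least 20 plants. Groups were taken from the sample titles, and in 6 Col libraries titled 30 min the time characteristic reads 0 min. One table of genes by libraries was used, without the raw reads. Its deposited values are a signal on a linear scale: gene read counts that the authors divided by one size factor per library. The labels name cutadapt 1.18, FastQC 0.11.7, STAR 2.4.0.1, DESeq2 1.20.0 and the genome build TAIR10, and the counting tool and strand are not given in the sources used here. Multiplied by the size factor, 100% of 1084756 values above 0 came out whole within 1e-06, and the factors (0.776 to 1.17) equal the median-of-ratios factors over all libraries. Read counts for edgeR and DESeq2 were recovered in this way. Between libraries of a group the chi-square per gene was 15.9 to 71.3 over 48 pairs, so spread between libraries exceeds counting error. Of 32833 genes, 5123 were at 0 in every library and 32548 matched an identifier of the TAIR10.1 annotation, which gave the symbols.

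Genes with a mean value of at least 10 (19556) were tested with limma 3.58.1 (R 4.3.3, empirical Bayes with trend) on log2 of the value plus 1. A single fit of 16 group means to all libraries gave each contrast, with Benjamini-Hochberg adjustment within it and a threshold of 0.05. Contrasts were each time against 0 min per genotype and leaf, myb30 against Col per leaf and time, genotype by time, and leaf by time in Col. The sign of a change is later time minus 0 min, myb30 minus Col, or local minus systemic. These contrasts, the threshold, the rule for named genes, the gene lists and most alternatives were set before the data were examined. The genotype comparisons after 0 min and the direct comparisons of local with systemic leaves were added afterwards, as were the fits without the 3 outlying 0 min libraries, with the libraries in doubt exchanged and without both of them.

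Named genes were the 5 highest and 5 lowest called genes per Col response with a mean of at least 50 in the higher group and no overlap between the libraries, 7 and 7 per genotype comparison (for those after 0 min, the rule was extended after the data were seen), and 3 and 3 per interaction. Where none passed, the 3 with the smallest p are given as values. MYB30, up to 4 members of each described list, and for myb30 responses the genes named in Col were added. Genes at 0 or with 1 to 3 reads in a group are given as levels without a fold, except for interactions in the closing section. The 24 lists were written from textbook knowledge: ERF and CBF/DREB factors, MYB30 and related R2R3-MYB factors, ROS and calcium signal propagation, ROS-responsive zinc finger and NAC regulators, WRKY factors, abscisic acid synthesis and response, antioxidant enzymes and glutathione transferases, auxin response and shade growth, circadian clock genes (time-of-day check), dark and sugar-starvation induced genes, dividing and young tissue markers, epidermis, trichome and myrosin cell markers, guard cell markers, heat shock proteins and factors, high-light and light-signalling genes, jasmonate synthesis and response, leaf senescence markers, nuclear-encoded photosynthesis proteins, phenylpropanoid, flavonoid and anthocyanin synthesis, reference genes, salicylate and immune genes, touch and calcium-sensor genes, vascular markers and very-long-chain fatty acid and wax synthesis, named MYB30 targets included. Lists with at least 4 tested members were tested with camera (preset correlation 0.01, adjusted over lists), and again with an estimated correlation.

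Alternatives were edgeR 4.0.16 quasi-likelihood (TMM), DESeq2 1.42.0 Wald tests (without an adjusted p for 1 to 15166 genes), pseudocounts of 0.5 and 8, no filter, quantile normalization, scaling to the same total, the compared groups fitted alone, a threshold of 0.01 for shared calls, a block for the library number, and each library or number left out. Library numbers were checked as pairs: libraries of the same number correlated above 0.1 in every pair in 5 of 20 comparisons (Col systemic 30 min, myb30 local 2 min, and myb30 against Col in local leaves at 0 and 2 min and systemic leaves at 8 min), which were taken as paired, as were local with systemic leaves at 2 and 8 min in Col and at 0, 2 and 8 min in myb30, and the labels do not say what a number means. Tools were tested on simulated data with changes of 1.25, 1.5, 2 and 4-fold placed in 50 genes each. Of these limma recovered 22%, 66%, 90% and 96% in Col systemic leaves at 2 min, with 9 of 146 calls false, and 8%, 48%, 84% and 92% in the local genotype interaction at 30 min, with 10 of 126 false. False calls were 9 of 146 and 6 of 119 with edgeR and 19 of 164 and 18 of 140 with DESeq2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.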

Results

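RNA from rosette leaves of 4-week-old Arabidopsis thaliana plants of the wild type Col-0 (Col) and of the myb30 mutant was sequenced after 0, 2, 8 or 30 min of high light on part of the rosette. MYB30 is an R2R3-MYB transcription factor. Local leaves stood in the high light, and systemic leaves of the same plants did not. The 16 groups of genotype, leaf and time held 3 libraries each, 48 in all, each from a pool of plants. Libraries held 70514715 to 89402096 reads counted in genes, and 22302 to 23117 of 32833 listed genes had a value above 0. Levels are mean normalised read counts ± SD (n = 3). Changes are log2 fold changes ± standard error from limma over 19556 tested genes. The p-values measure the spread between these samples. Of 225 camera calls, 11 held with an estimated correlation, most of them of heat shock genes.

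The labels of 2 libraries were in doubt. Of the tested genes, 8 parted the 21 Col from the 21 myb30 libraries outside systemic 0 min without overlap, 5 lower and 3 higher in myb30. In Col systemic 0 min replicate 3 and in myb30 systemic 0 min replicate 3, 100% of these genes lay nearer the mean of the other genotype, against at most 12.5% in any other library. The non-coding RNA AT2G06995 stood at 21.9 in the first and 125 in the second, where Col and myb30 libraries outside systemic 0 min ranged from 64.0 to 195 and from 6.48 to 32.7. AT1G75945 stood at 891 and 258, against 24.1 to 278 in Col and 468 to 955 in myb30. The stress factor WRKY40 (AT1G80840) stood at 1897 in Col local 0 min replicate 3, 496 in Col systemic 0 min replicate 1 and 3317 in myb30 systemic 0 min replicate 3, and at 33.6 to 60.9 in the other 0 min libraries, and counts without these are given where they moved. Groups follow the labels here, and counts of called genes that use systemic 0 min leaves are also given with the libraries in doubt exchanged between the genotypes, as are list counts that this moved beyond 1.5 times, both alternatives chosen after the data were seen. Counts with libraries left out follow the labels, and a number stands for that replicate of every group.

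**Figure D1:**
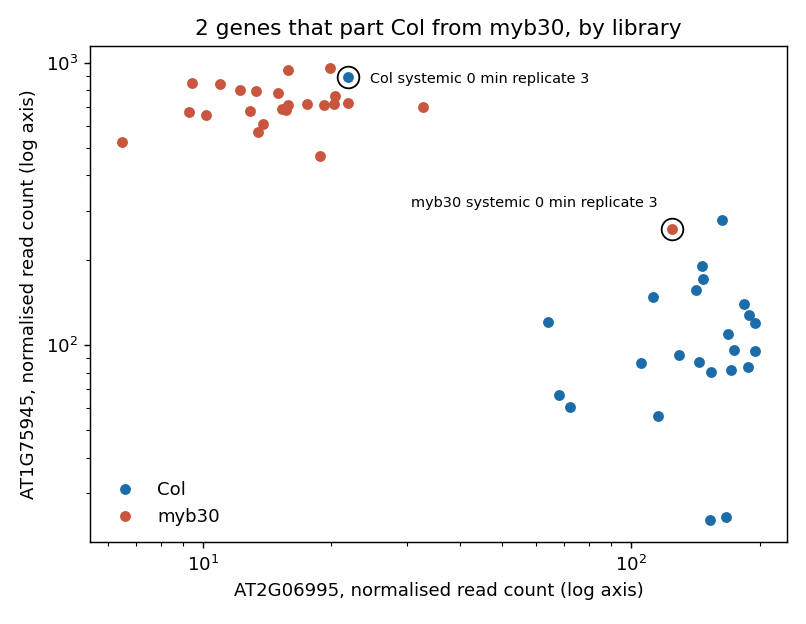
Normalised read counts (log axes) of AT2G06995 and AT1G75945 in each of 48 libraries, coloured by the labelled genotype. Replicate 3 of Col systemic 0 min (21.9 and 891) lies among the myb30 libraries, and that of myb30 (125 and 258) among those of Col.

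Transcripts of MYB30 (AT3G28910), the gene named for the mutant, were present in both genotypes. In Col local leaves they stood at 679 ± 121, 808 ± 52.9, 564 ± 55.2 and 272 ± 43.7 at 0, 2, 8 and 30 min, and in Col systemic leaves at 616 ± 177, 816 ± 25.1, 956 ± 98.1 and 729.6 ± 26.6. In myb30 the local values were 447 ± 53.9, 518 ± 171, 391 ± 66.7 and 204 ± 24.3, and the systemic ones 709 ± 159, 571 ± 228, 510.3 ± 52.5 and 508 ± 37.5. MYB30 fell in local leaves at 30 min in Col (-1.31 ± 0.22, adjusted p = 4.71e-06) and in myb30 (-1.13, adjusted p = 6.18e-05), rose in Col systemic leaves at 8 min (0.67, adjusted p = 0.0245), and had a lower local change in the tissue comparison at 30 min (-1.60 ± 0.31, adjusted p = 7.73e-05). The log2 ratio of myb30 to Col, with a standard error of 0.22, was -0.59, -0.69, -0.54 and -0.41 in local leaves over time and 0.22, -0.59, -0.90 and -0.52 in systemic leaves. Adjusted over all genes, MYB30 passed in none of these 8 comparisons by limma, and DESeq2 called it at 8 min in systemic leaves (-0.91). In each comparison but systemic 0 and 2 min all Col libraries lay above all of myb30. With the exchange the value in systemic leaves at 0 min was -0.38, and the rise in Col systemic leaves at 8 min was 0.37, or 0.41 without Col systemic 0 min replicate 3, and did not pass. Without that library the value at 0 min was -0.0379, and -0.12 without replicate 3 of every group. Reads counted over a whole gene do not check the mutant allele.

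**Figure D2:**
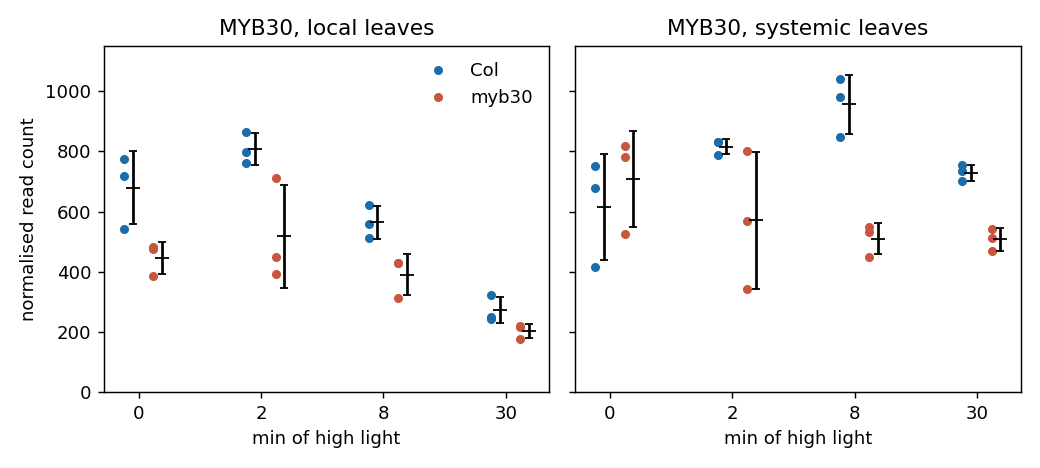
Normalised read count of MYB30 in each library against minutes of high light, for local and systemic leaves of Col and myb30, with group means and SD (n = 3) as bars beside the points. Means in local leaves at 30 min were 272 in Col and 204 in myb30.

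In Col local leaves at 2 min 1158 genes rose and 928 fell. The highest were the CAP-family gene AT1G01310 (4.15 ± 0.57, adjusted p = 5.61e-05), the pectin methylesterase inhibitor PMEI1 (AT1G48020, 3.05 ± 0.53), the small heat shock gene AT1G59860 (2.57 ± 0.37), the DnaJ chaperone AT1G56300 (2.34 ± 0.45) and the cold-response factor CBF3 (AT4G25480, 2.17 ± 0.49). The lowest were the epidermal gene PDF1 (AT2G42840, -4.20 ± 0.76, adjusted p = 0.000812), from 327 ± 109 to 16.5 ± 4.62, the delta-9 desaturases AT1G06080 (-3.08 ± 0.72) and AT1G06360 (-2.42 ± 0.40), the lipase LTL1 (AT3G04290, -2.94 ± 0.47) and the glycine-rich protein AT4G29020 (-2.84 ± 0.43). Of 18 tested high-light and light-signalling genes, 1 rose and 7 fell, or 1 and 10 adjusted over the list alone (median -0.41, camera adjusted p = 0.00367, or 0.746 with an estimated correlation). The UV-B pathway repressors RUP1 (AT5G52250, -0.67 ± 0.15) and RUP2 (AT5G23730, -0.53 ± 0.15) and the bZIP factor HYH (AT3G17609, -0.83 ± 0.20) fell, while the xanthophyll-cycle enzyme VDE (AT1G08550, 0.55 ± 0.0969) rose. Among the nuclear photosynthesis genes, 15 of 29 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 0.21, camera adjusted p = 1.10e-08, or 0.746 with an estimated correlation). The photosystem antenna genes LHCA1 (AT3G54890, 0.34 ± 0.0626) and LHCB1.2 (AT1G29910, 0.33 ± 0.0661) were among those that rose. The 15 tested phenylpropanoid, flavonoid and anthocyanin genes had 0 higher and 3 lower members, with 0 and 5 adjusted over the list alone (median -0.40, camera adjusted p = 0.0166, or 0.746 with an estimated correlation). The enzyme C4H (AT2G30490, -0.50 ± 0.13) and the flavonol regulator MYB111 (AT5G49330, -1.68 ± 0.55) fell. Of the called genes 55.5% were higher, against 32.5% scaled to the same total. Other fits moved the 2086 calls to 620 with the compared groups alone and 946 without the 3 outlying libraries. Leaving out libraries gave 73 and 214 without numbers 2 and 3, 783 and 969 without Col local 0 min replicates 2 and 3, and 1340 and 314 without Col local 2 min replicates 2 and 3.

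By 8 min heat shock genes led the response of Col local leaves, in which 2603 genes rose and 2476 fell. The DnaJ gene AT1G71000 (10.39 ± 0.78, adjusted p = 6.78e-13) rose from 2.39 ± 1.23 to 4481 ± 1645, the cytosolic small heat shock proteins HSP17.6C (AT1G53540, 9.47 ± 0.89) and HSP17.6A (AT5G12030, 9.03 ± 0.75) rose with it, and so did mitochondrial HSP23.6 (AT4G25200, 9.39 ± 0.78) and endoplasmic HSP22.0 (AT4G10250, 9.34 ± 1.03). Of 27 tested heat shock proteins and factors, 27 rose and 0 fell, also adjusted over the list alone (median 5.90, camera adjusted p = 1.37e-59, or 1.03e-06 with an estimated correlation). Among them were the co-chaperone BAG6 (AT2G46240, 8.15 ± 0.21), peroxisomal HSP15.7 (AT5G37670, 7.09 ± 0.23), the chaperone HSP70B (AT1G16030, 5.08 ± 0.18) and the regulator DREB2A (AT5G05410, 6.15 ± 0.27). Among the ERF and CBF/DREB factors, 14 of 18 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 2.63, camera adjusted p = 2.64e-08, or 0.458 with an estimated correlation). The factors RAP2.4 (AT1G78080, 1.57 ± 0.11) and CBF2 (AT4G25470, 3.21 ± 0.58) rose. The lowest genes were PDF1 (-4.56 ± 0.76), AT1G06080 (-3.46 ± 0.72), AT4G29020 (-3.28 ± 0.43), LTL1 (-2.98 ± 0.47) and AT1G06360 (-2.93 ± 0.40). Higher genes made up 51.3% of the calls, against 35.5% after quantile normalization and 22.3% scaled to the same total, which moved the median of all genes by -0.12. The 5079 called genes became 2910 with the compared groups alone. Omitting libraries gave 2912 and 2066 without numbers 2 and 3, and 3056 without Col local 8 min replicate 3.

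At 30 min of high light 5315 genes rose and 5192 fell in Col local leaves. HSP22.0 went from 2.06 ± 2.11 to 56096 ± 5177, AT1G71000 (13.89 ± 0.78, adjusted p = 2.44e-17), HSP23.6 (13.33 ± 0.78) and HSP17.6C (13.18 ± 0.89) rose, and the chloroplast HSP21 (AT4G27670) stood at 0.660 ± 0.572 at 0 min and 18869 ± 723 at 30 min. The lowest were the SAUR gene AT4G34770 (-4.98 ± 0.52, adjusted p = 4.29e-10), PDF1 (-4.68 ± 0.76), AT1G06080 (-4.32 ± 0.72), the lipid-transfer family gene AT5G48490 (-4.05 ± 0.23) and AT1G06360 (-3.91 ± 0.40). Of 18 tested high-light and light-signalling genes, 14 rose and 1 fell, also adjusted over the list alone (median 1.31, camera adjusted p = 5.32e-07, or 0.0974 with an estimated correlation). The peroxidases APX2 (AT3G09640, 10.35 ± 0.39) and APX1 (AT1G07890, 2.32 ± 0.13) and the early light-induced ELIP1 (AT3G22840, 3.19 ± 0.20) rose. Among the jasmonate synthesis and response genes, 20 of 20 rose and 0 fell, also adjusted over the list alone (median 3.63, camera adjusted p = 1.47e-06, or 0.428 with an estimated correlation). The repressor JAZ1 (AT1G19180, 5.91 ± 0.82) and the synthesis enzyme AOC3 (AT3G25780, 5.18 ± 0.83) were among them. Of 27 tested abscisic acid genes, 20 rose and 0 fell, or 22 and 0 adjusted over the list alone (median 0.96, camera adjusted p = 8.77e-07, or 0.271 with an estimated correlation). The dehydrins COR47 (AT1G20440, 2.66 ± 0.17) and ERD10 (AT1G20450, 3.15 ± 0.23) rose. Among the antioxidant and glutathione transferase genes, 13 of 19 rose and 2 fell, also adjusted over the list alone (median 1.58, camera adjusted p = 0.000928, or 0.0974 with an estimated correlation). Glutathione transferases GSTU19 (AT1G78380, 2.06 ± 0.0927) and GSTF8 (AT2G47730, 2.71 ± 0.16) rose. The 9 tested dark and sugar-starvation genes had 0 higher and 8 lower members, with 0 and 9 adjusted over the list alone (median -1.10, camera adjusted p = 0.000289, or 0.20 with an estimated correlation). The trehalose-phosphate synthase family members TPS8 (AT1G70290, -1.95 ± 0.15) and TPS11 (AT2G18700, -1.92 ± 0.16) fell. Of 14 tested auxin and shade-growth genes, 2 rose and 9 fell, also adjusted over the list alone (median -0.92, camera adjusted p = 0.00135, or 0.124 with an estimated correlation). The shade-growth factor PIF5 (AT3G59060, -0.98 ± 0.0571) and the auxin carrier PIN3 (AT1G70940, -1.61 ± 0.10) fell. The share of higher genes among the calls was 50.6%, against 36.8% after quantile normalization and 16.7% scaled to the same total, which moved the median of all genes by -0.34.

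Further lists were examined in Col local leaves at 30 min. Among the very-long-chain fatty acid and wax genes, 0 of 16 rose and 9 fell, also adjusted over the list alone (median -0.56, camera adjusted p = 0.0258, or 0.644 with an estimated correlation). The acyl thioesterase FATB (AT1G08510, -0.27 ± 0.0795) and the wax enzyme CER4 (AT4G33790, -2.18 ± 0.57) fell. Of 7 tested guard cell markers, 1 rose and 5 fell, also adjusted over the list alone (median -0.74, camera adjusted p = 0.0306, or 0.428 with an estimated correlation). Higher and lower, also adjusted over the list alone, were 7 and 4 of 15 ROS and calcium propagation genes (median 0.26, camera adjusted p = 0.443), 1 and 3 of 5 MYB30-related factors (median -0.96, camera adjusted p = 0.392), 1 and 1 of 9 vascular markers (median -0.0748, camera adjusted p = 0.927), 0 and 1 of 5 epidermal, trichome and myrosin cell markers (median -0.0969, camera adjusted p = 0.591), 1 and 1 of 5 dividing-tissue markers (median 0.27, camera adjusted p = 0.924), 2 and 1 of 5 senescence markers (median 0.35, mean -0.24, camera up, camera adjusted p = 0.509) and 2 and 0 of 6 reference genes (median 0.0915, camera adjusted p = 0.392).

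In systemic Col leaves 1244 genes rose and 1071 fell at 2 min. The DnaJ gene AT1G56300 (2.71 ± 0.45, adjusted p = 0.000317) and CBF3 (2.58 ± 0.49) again stood among the highest, with the major facilitator AT1G22570 (2.59 ± 0.49), MEE14 (AT2G15890, 2.49 ± 0.38) and the RING protein AT1G49230 (2.43 ± 0.39). The lowest were the Dof factor AT1G26790 (-2.03 ± 0.56), AT5G05965 (-1.38 ± 0.40), the beta-amylase family gene BMY3 (AT5G18670, -1.36 ± 0.34), the morning clock gene LHY (AT1G01060, -1.33 ± 0.31) and the heat shock factor HSFA7A (AT3G51910, -1.29 ± 0.41). LHY went from 30042 ± 5519 to 12059 ± 3136. Of 18 tested high-light and light-signalling genes, 1 rose and 10 fell, or 2 and 10 adjusted over the list alone (median -0.51, camera adjusted p = 0.000385, or 0.428 with an estimated correlation). The 12 tested circadian clock genes had 3 higher and 5 lower members, with 4 and 5 adjusted over the list alone (median 0.0106, the mean was 0.00944 and camera pointed down, camera adjusted p = 0.798). With the exchange 660 genes were higher and 649 lower, and of the 10 named genes AT5G05965 and HSFA7A no longer passed. Against 2315 calls there were 634 with the compared groups alone and 1128 without both libraries in doubt. Left-out libraries gave 456 and 269 without numbers 2 and 3, 1132 without Col systemic 0 min replicate 3, and 1203 and 480 without Col systemic 2 min replicates 2 and 3.

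Systemic Col leaves at 8 min had 2162 higher and 2223 lower genes. The homoterpene enzyme CYP82G1 (AT3G25180, 5.74 ± 1.80, adjusted p = 0.0204), the geranyllinalool synthase TPS04 (AT1G61120, 5.49 ± 1.97) and the cold-response factor CBF1 (AT4G25490, 5.61 ± 1.07) rose. The terpene synthase AT2G24210 stood at 0 ± 0 at 0 min and 203 ± 279 at 8 min, and jasmonate-regulated JRG21 (AT3G55970) at 0.617 ± 1.07 and 93.9 ± 95.7. Small heat shock genes AT1G07400 (-2.77 ± 0.58, adjusted p = 0.000997) and HSP17.6A (-2.54 ± 0.75), the heat shock factor HSFA2 (AT2G26150, -2.02 ± 0.59), AT1G26790 (-2.45 ± 0.56) and the glycerophosphodiesterase SRG3 (AT3G02040, -1.92 ± 0.59) fell most. Of 27 tested heat shock proteins and factors, 0 rose and 13 fell, or 1 and 15 adjusted over the list alone (median -1.07, camera adjusted p = 0.000121, or 0.435 with an estimated correlation). The chaperone HSP90.1 (AT5G52640, -1.87 ± 0.37) and mitochondrial HSP23.5 (AT5G51440, -1.35 ± 0.29) fell. Among the ERF and CBF/DREB factors, 14 of 18 rose and 0 fell, or 16 and 0 adjusted over the list alone (median 3.20, camera adjusted p = 1.98e-08, or 0.328 with an estimated correlation). CBF3 (3.22 ± 0.49), CBF2 (3.18 ± 0.58) and the jasmonate-responsive ORA47 (AT1G74930, 4.84 ± 0.91) rose. With the exchange 7 of 18 ERF and CBF/DREB factors rose and 0 fell (median 1.74) and 0 of 27 heat shock proteins and factors rose and 10 fell (median -0.77). The exchange gave 1437 higher and 1688 lower genes, and of the 10 named genes CYP82G1, TPS04, JRG21 and HSP17.6A no longer passed. Other fits moved the 4385 calls to 1859 with the compared groups alone. Dropping libraries gave 2654 and 1542 without numbers 1 and 3, and 2000 without Col systemic 8 min replicate 3.

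Jasmonate and sugar-starvation genes rose together in systemic Col leaves at 30 min, where 3453 genes rose and 3334 fell. The highest by the rule were CYP82G1 (7.74 ± 1.80, adjusted p = 0.000972), the repressor JAZ7 (AT2G34600, 7.47 ± 1.41) and TPS04 (7.35 ± 1.97), and levels from 0 to 30 min were 0 ± 0 and 284 ± 338 for AT2G24210 and 0.617 ± 1.07 and 247 ± 268 for JRG21. The lowest were AT1G26790 (-4.04 ± 0.56, adjusted p = 8.00e-07), AT3G24750 (-3.01 ± 0.38), the GATA factor CGA1 (AT4G26150, -2.91 ± 0.24), the B-box factor BBX32 (AT3G21150, -2.56 ± 0.25) and MYB13 (AT1G06180, -2.53 ± 0.37). Among the jasmonate synthesis and response genes, 20 of 20 rose and 0 fell, also adjusted over the list alone (median 3.81, camera adjusted p = 4.07e-12, or 0.293 with an estimated correlation). The synthesis enzyme AOC2 (AT3G25770, 3.17 ± 0.47) and the repressors JAZ3 (AT3G17860, 1.81 ± 0.28) and JAZ1 (4.98 ± 0.82) rose. The 9 tested dark and sugar-starvation genes had 9 higher and 0 lower members, also adjusted over the list alone (median 1.14, camera adjusted p = 3.80e-09, or 0.0633 with an estimated correlation). TPS11 (2.55 ± 0.16), its relatives AT1G60140 (0.89 ± 0.0863) and TPS8 (1.38 ± 0.15), and the asparagine synthetase DIN6 (AT3G47340, 1.88 ± 0.27) rose. Of 18 tested high-light and light-signalling genes, 2 rose and 11 fell, also adjusted over the list alone (median -0.96, camera adjusted p = 1.90e-05, or 0.243 with an estimated correlation). After the exchange 2986 genes were higher and 3110 lower, and all 10 named genes passed with the same sign.

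The overlap of local and systemic Col responses addressed how far unlit leaves held the response of lit ones. These comparisons share plants and harvests but no library. Both leaves of a number deviated together (correlations 0.116 to 0.587 over pairs at 2 and 8 min), so the calls are not independent. At 2 min, 688 genes rose in both leaves, among them AT1G56300 and CBF3, and 398 fell in both. At 8 min the shared genes were 1119 higher and 922 lower. At 30 min they were 1673 and 1360, while 660 genes rose locally and fell systemically and 537 did the reverse. JAZ1 rose in both leaves at 30 min, and TPS11 fell in local and rose in systemic leaves. With the exchange the shared genes were 473 higher and 337 lower at 2 min, 807 higher and 864 lower at 8 min and 1459 higher and 1297 lower at 30 min. These counts carry no test.

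**Figure D3:**
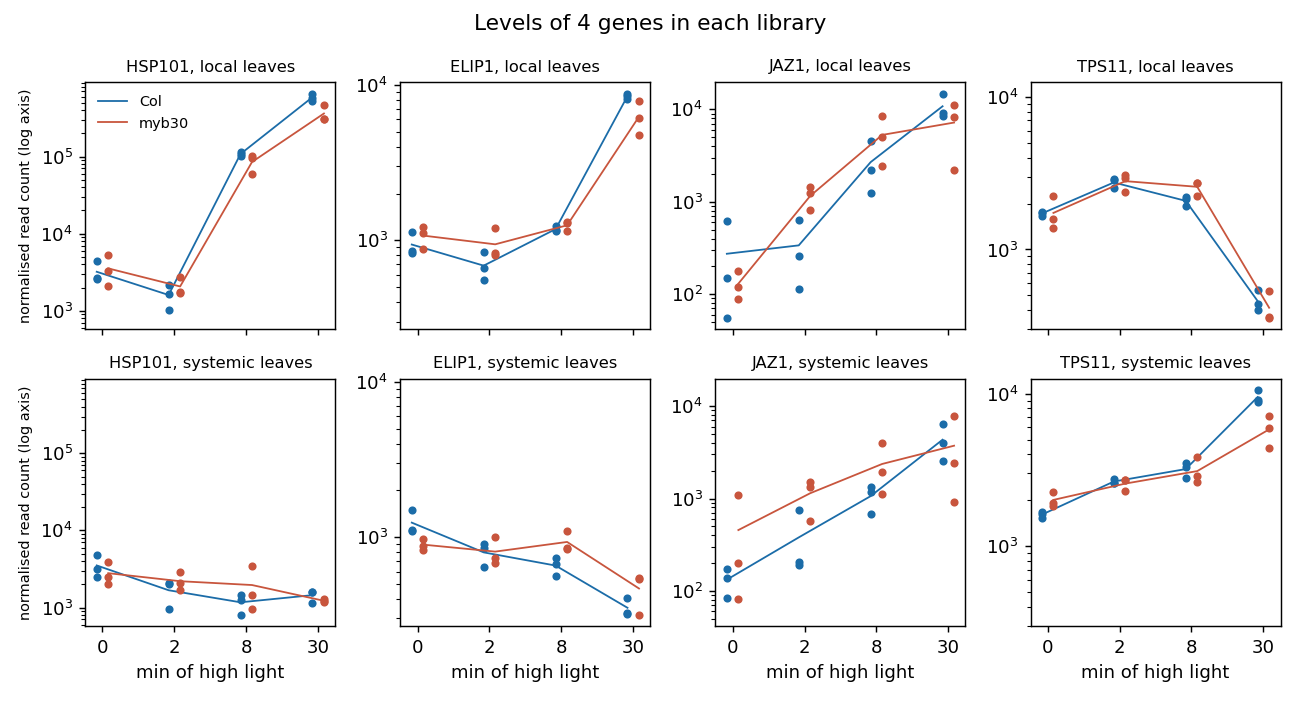
Normalised read count (log axis) of HSP101, ELIP1, JAZ1 and TPS11 against minutes of high light in local and systemic leaves of Col and myb30, with points for libraries and lines through group means (n = 3). In local leaves at 30 min, Col libraries lie above all of 0 min for HSP101 and below them for TPS11.

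Whether the lit leaf changed more than the unlit one was tested as an interaction in Col, as the local minus the systemic change. At 2 min 7 genes had a higher and 1 a lower local change. The interaction was positive for AT1G01310 (4.74 ± 0.81, adjusted p = 0.00448), PMEI1 (3.96 ± 0.75) and AT1G59860 (3.46 ± 0.52), and negative for LTL1 (-3.42 ± 0.67, adjusted p = 0.0286). Exchanged libraries gave 6 higher and 0 lower genes, and of the 4 named genes PMEI1 and LTL1 no longer passed. Other settings moved the 8 genes to 0 with the compared groups alone. Fewer libraries gave 3, 1 and 0 without numbers 1, 2 and 3, and 16 without Col systemic 0 min replicate 2.

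The local change at 8 min exceeded the systemic one for 517 genes and was under it for 294. HSP17.6A (11.57 ± 1.05, adjusted p = 2.05e-10) had one of the highest interactions. From 0 to 8 min AT1G71000 went from 2.39 ± 1.23 to 4481 ± 1645 in local leaves and from 6.83 ± 7.55 to 0.642 ± 0.556 in systemic leaves, and HSP23.6 from 13.3 ± 5.23 to 9211 ± 912 and from 18.7 ± 15 to 4.67 ± 3.3. PDF1 (-5.28 ± 1.08), LTL1 (-3.80 ± 0.67) and AT1G06080 (-3.58 ± 1.02) had the lowest. The 27 tested heat shock proteins and factors had 26 higher and 0 lower members, also adjusted over the list alone (median 6.91, camera adjusted p = 8.57e-106, or 1.66e-09 with an estimated correlation). With the exchange 446 genes were higher and 227 lower, and of the 6 named genes AT1G06080 no longer passed. Among called genes, 63.7% were higher, against 52.1% after quantile normalization and 28.7% scaled to the same total, which moved the median of all genes by -0.13. Against 811 calls there were 1305 scaled to the same total, 439 with the compared groups alone, 1655 with a replicate block by pool of plants and 487 without the 3 outlying libraries. Leaving out libraries gave 398, 460 and 307 without numbers 1, 2 and 3.

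After 30 min the changes of 7206 genes differed between lit and unlit Col leaves, 3597 with a higher and 3609 with a lower local change. HSP22.0 went from 2.06 ± 2.11 to 56096 ± 5177 in local leaves and from 3.25 ± 3.51 to 1.23 ± 2.12 in systemic leaves. HSP23.6 and AT1G71000 reached 141300.0 ± 8363 and 49217 ± 7792 locally and 6.22 ± 2.00 and 2.52 ± 1.89 systemically. The interaction was lowest for PDF1 (-5.63 ± 1.08), the zinc finger gene ATCTH (AT2G25900, -5.25 ± 0.29, adjusted p = 4.86e-17) and the sugar-starvation gene AT3G15450 (-5.14 ± 0.33). The 27 tested heat shock proteins and factors had 27 higher and 0 lower members, also adjusted over the list alone (median 9.58, camera adjusted p = 1.55e-40, or 3.82e-05 with an estimated correlation). The 18 tested high-light and light-signalling genes had 15 higher and 1 lower members, also adjusted over the list alone (median 2.00, camera adjusted p = 3.28e-12, or 0.00914 with an estimated correlation). APX2 (11.39 ± 0.56), ELIP1 (5.0 ± 0.28) and the B-box gene BBX31 (AT3G21890, 4.43 ± 0.30) had higher local changes. The 9 tested dark and sugar-starvation genes had 0 higher and 9 lower members, also adjusted over the list alone (median -2.31, camera adjusted p = 6.16e-10, or 0.0157 with an estimated correlation). TPS11 and TPS8 had interactions of -4.47 ± 0.23 and -3.33 ± 0.21. The 20 tested jasmonate synthesis and response genes had 0 higher and 0 lower members, also adjusted over the list alone (median -0.0435, camera adjusted p = 0.947). The exchange gave 3637 higher and 3484 lower genes, and all 6 named genes passed with the same sign. Of the called genes 49.9% were higher, against 39.3% after quantile normalization and 16.4% scaled to the same total, which moved the median of all genes by -0.32.

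In myb30 local leaves at 2 min 290 genes rose and 35 fell, and the 5 genes named as highest in Col rose too. AT1G01310 (3.78 ± 0.57, adjusted p = 0.000219), PMEI1 (2.66 ± 0.53), AT1G59860 (1.79 ± 0.37), AT1G56300 (1.79 ± 0.45) and CBF3 (2.25 ± 0.49) rose. PDF1, at 25.5, 23.3 and 277 in 0 min libraries and 21.3 ± 8.64 at 2 min, did not pass. Low PDF1 thus also occurred without high light. Of 18 tested ERF and CBF/DREB factors, 9 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 3.3, camera adjusted p = 2.50e-22, or 0.0271 with an estimated correlation). CBF2 (3.91 ± 0.58), ORA47 (5.70 ± 0.91) and CBF1 (6.23 ± 1.07) rose. Among the WRKY factors, 4 of 13 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.73, camera adjusted p = 3.39e-08, or 0.209 with an estimated correlation). WRKY11 (AT4G31550, 0.49 ± 0.10), WRKY40 (5.53 ± 1.15) and WRKY33 (AT2G38470, 2.35 ± 0.51) rose. The 6 tested touch and calcium-sensor genes had 2 higher and 0 lower members, with 4 and 0 adjusted over the list alone (median 1.08, camera adjusted p = 4.21e-05, or 0.290 with an estimated correlation). Both the calmodulin-like TCH2 (AT5G37770, 1.00 ± 0.25) and the wall enzyme TCH4 (AT5G57560, 2.68 ± 0.71) rose. Higher genes made up 89.2% of the calls, against 78.6% after quantile normalization. The 325 called genes became 151 with the compared groups alone, 569 with a replicate block and 561 by DESeq2. Omitting libraries gave 38, 71 and 166 without numbers 1, 2 and 3, 515, 174 and 98 without myb30 local 0 min replicates 1, 2 and 3, and 63 without myb30 local 2 min replicate 1.

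Heat shock genes also rose in myb30 local leaves at 8 min, where 1853 genes rose and 1808 fell. AT1G71000 (8.87 ± 0.78, adjusted p = 6.75e-11), HSP17.6C (9.41 ± 0.89), HSP17.6A (7.66 ± 0.75) and HSP23.6 (9.19 ± 0.78) rose, and HSP22.0 went from 0.311 ± 0.539 to 1188 ± 449. Of the genes named as lowest in Col, AT4G29020 (-1.22 ± 0.43) and AT1G06360 (-1.29 ± 0.40) fell, and the others did not pass. AT4G29020 (-0.65) did not pass without myb30 local 0 min replicate 3. The share of higher genes among the calls was 50.6%, against 32.9% after quantile normalization. Other settings moved the 3661 genes to 1867 with the compared groups alone. Left-out libraries gave 2405, 2051 and 1738 without numbers 1, 2 and 3, 2427 and 2022 without myb30 local 0 min replicates 2 and 3, and 2221 without myb30 local 8 min replicate 1.

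By 30 min 4393 genes rose and 4223 fell in myb30 local leaves, and each of the 10 genes named in Col passed with the same sign. AT1G71000 (12.48 ± 0.78, adjusted p = 8.07e-16), HSP23.6 (12.78 ± 0.78) and HSP17.6C (12.73 ± 0.89) rose, HSP21 reached 9907 ± 3218 from 0 ± 0, and PDF1 (-2.50 ± 0.76), AT4G34770 (-4.05 ± 0.52) and AT5G48490 (-3.41 ± 0.23) fell, though PDF1 (-1.35) did not pass without myb30 local 0 min replicate 3. The 27 tested heat shock proteins and factors had 27 higher and 0 lower members, also adjusted over the list alone (median 8.04, camera adjusted p = 4.63e-38, or 6.53e-05 with an estimated correlation). Among called genes, 51.0% were higher, against 38.0% after quantile normalization and 26.4% scaled to the same total, which moved the median of all genes by -0.16.

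In systemic myb30 leaves at 2 min limma, edgeR and DESeq2 called 0 genes, with 930 at an unadjusted p under 0.05 by limma. AT1G56300 stood at 204 ± 59.8 at 0 min and 381 ± 152 at 2 min, and CBF3 at 129.6 ± 17.3 and 352 ± 52.2. Of the 10 genes named in Col, 9 had the same sign in myb30 and 0 passed. Of those called in Col, 85.3% of the higher and 81.9% of the lower had the same sign. After the exchange 62 genes were higher and 1 lower. Among them, chosen after the values were seen, were the factors CBF2 (3.24 ± 0.56), ORA47 (5.03 ± 0.95) and ZAT10 (AT1G27730, 4.27 ± 0.84) and the calmodulin-like CML38 (AT1G76650, 4.76 ± 0.93). The 0 called genes became 81 without the 3 outlying libraries and 52 without both libraries in doubt. Dropping libraries gave 30 without number 3, 55 without myb30 systemic 0 min replicate 3, and 1 without myb30 systemic 2 min replicate 2.

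At 8 min 146 genes rose and 26 fell in myb30 systemic leaves. Of 18 tested ERF and CBF/DREB factors, 6 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 2.71, camera adjusted p = 5.34e-18, or 0.0730 with an estimated correlation). CBF2 (3.04 ± 0.58, adjusted p = 0.00658) and the repressor ERF4 (AT3G15210, 1.36 ± 0.31) rose. Among the ROS-responsive zinc finger and NAC regulators, 4 of 18 rose and 0 fell, or 8 and 1 adjusted over the list alone (median 0.86, camera adjusted p = 6.36e-08, or 0.106 with an estimated correlation). The zinc finger repressors ZAT6 (AT5G04340, 2.55 ± 0.47) and AZF2 (AT3G19580, 1.5 ± 0.32) rose. CYP82G1 stood at 9.35 ± 16.2 at 0 min and 108 ± 156 at 8 min without passing, and 0 of the 10 genes named in Col passed. Exchanged libraries gave 375 higher and 82 lower genes. Then 13 of 18 ERF and CBF/DREB factors rose and 0 fell (median 3.77). The share of higher genes among the calls was 84.9%, against 71.4% after quantile normalization. Other settings moved the 172 genes to 3 with the compared groups alone, 94 by edgeR, 267 by DESeq2, 267 without the 3 outlying libraries and 259 without both libraries in doubt. Fewer libraries gave 1, 14 and 262 without numbers 1, 2 and 3, 7 and 21 without myb30 systemic 0 min replicates 1 and 2, and 2, 297 and 99 without myb30 systemic 8 min replicates 1, 2 and 3.

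Jasmonate genes rose in myb30 systemic leaves at 30 min as they had in Col, and 1148 genes rose and 1125 fell. CYP82G1 (6.03 ± 1.80, adjusted p = 0.0243) and JAZ7 (5.05 ± 1.41) rose, AT1G26790 (-2.74 ± 0.56), AT3G24750 (-1.76 ± 0.38), CGA1 (-1.76 ± 0.24) and BBX32 (-0.94 ± 0.25) fell, and TPS04 (5.21 ± 1.97) and MYB13 (-0.97 ± 0.37) did not pass. Among the jasmonate synthesis and response genes, 17 of 20 rose and 0 fell, or 20 and 0 adjusted over the list alone (median 2.79, camera adjusted p = 6.93e-15, or 0.224 with an estimated correlation). The 16 tested salicylate and immune genes had 4 higher and 0 lower members, with 7 and 0 adjusted over the list alone (median 1.35, camera adjusted p = 7.66e-06, or 0.352 with an estimated correlation). The immune regulators NPR1 (AT1G64280, 0.45 ± 0.12) and CBP60G (AT5G26920, 1.52 ± 0.44) and the salicylate transporter EDS5 (AT4G39030, 1.17 ± 0.34) rose. Among the dark and sugar-starvation genes, 4 of 9 rose and 0 fell, or 6 and 0 adjusted over the list alone (median 0.46, camera adjusted p = 9.01e-06, or 0.224 with an estimated correlation). With the exchange 1439 genes were higher and 1340 lower, and all 6 named genes passed with the same sign. Then 2 of 16 salicylate and immune genes rose and 0 fell (median 0.91), and EDS5 did not pass while TPS04 did. Against 2273 calls there were 692 with the compared groups alone, 1401 without the 3 outlying libraries and 1450 without both libraries in doubt. Leaving out libraries gave 1023, 597 and 1496 without numbers 1, 2 and 3, 1405 without myb30 systemic 0 min replicate 3, and 1214 and 1427 without myb30 systemic 30 min replicates 1 and 2.

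The overlap of Col and myb30 responses addressed how far the mutant held the genes of the wild type. In local leaves both genotypes called 126 higher and 22 lower genes at 2 min, where AT1G01310 and CBF3 were shared. At 8 min they shared 1425 higher and 1408 lower genes, with AT1G71000 among them, and at 30 min 3786 higher and 3575 lower genes, with TPS11 among the lower ones. In systemic leaves the shared calls were 124 higher and 17 lower genes at 8 min, with CBF2 among them, and 1012 higher and 1000 lower genes at 30 min, with JAZ7 and CYP82G1 among them. With the exchange Col and myb30 systemic leaves shared 0 higher and 0 lower genes at 2 min, 147 higher and 51 lower at 8 min and 1155 higher and 1124 lower at 30 min.

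**Figure D4:**
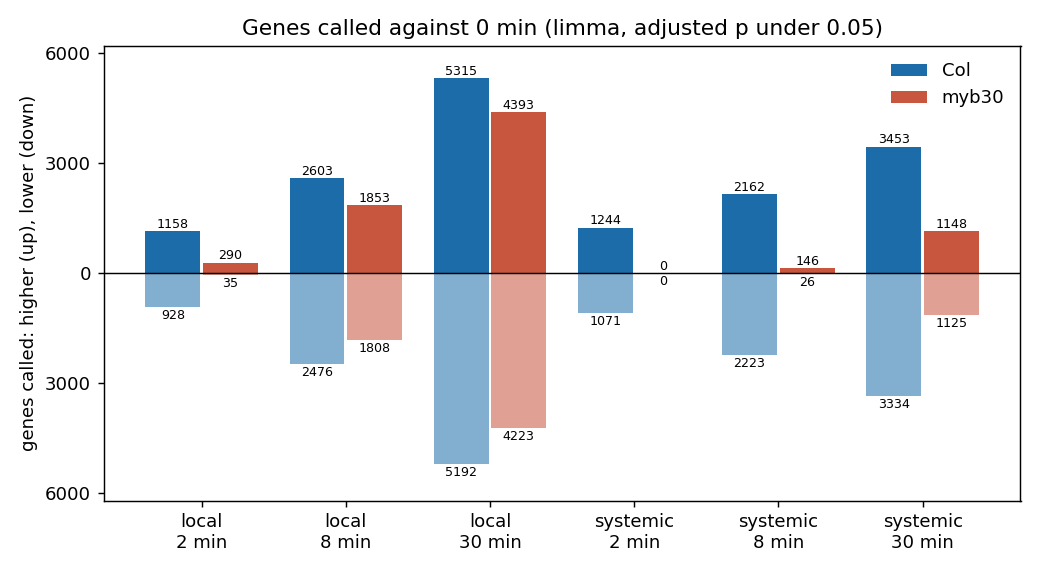
Genes called higher (bars up) and lower (bars down) than at 0 min, by leaf and time, in Col and myb30. Counts at 30 min in local leaves were 5315 and 5192 in Col and 4393 and 4223 in myb30.

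Direct comparison of myb30 with Col before high light addressed differences of the 2 lines in the resting state, which need not come from MYB30. In local leaves 0 genes were higher and 2 lower in myb30, of which the non-coding RNA AT2G06995 (-3.26 ± 0.54, adjusted p = 0.0123) stood at 15.3 ± 4.84 against 153 ± 36.4 in Col. The other, AT1G27565, chosen after its values were seen, was listed at 0 in all 3 myb30 libraries and at 26.8 ± 5.53 in Col, or at least 27.3-fold lower against a floor of 3 reads over the group. At an unadjusted p under 0.05 there were 873 genes in either direction by limma, and edgeR and DESeq2 called 1 and 10 genes in all. Other fits moved the 2 calls to 1 with a pseudocount of 8, 0 with the compared groups alone and 6 without the 3 outlying libraries. Omitting libraries gave 0, 0 and 4 without numbers 1, 2 and 3, 1, 0 and 0 without Col local 0 min replicates 1, 2 and 3, and 1 without myb30 local 0 min replicate 1.

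In local leaves at 2 min 62 genes were higher and 11 lower in myb30 than in Col. The highest were AT1G75945 (3.80 ± 0.56, adjusted p = 0.00141), the nuclease-like AT4G29780 (3.56 ± 0.83), BPS3 (AT4G01360, 3.45 ± 0.82), the abscisic acid hydroxylase CYP707A3 (AT5G45340, 3.3 ± 0.76), the wall enzyme TCH4 (3.1 ± 0.71), the mitochondrial carrier DIC2 (AT4G24570, 3.09 ± 0.74) and the small peptide gene AT3G10930 (3.01 ± 0.71). The lowest were the non-coding RNAs AT2G06995 (-3.43 ± 0.54, adjusted p = 0.00239), AT2G05914 (-2.61 ± 0.49) and AT3G05955 (-1.88 ± 0.43), the methylcytosine-binding VIM3 (AT5G39550, -0.88 ± 0.16), AT3G45230 (-0.43 ± 0.10), the spliceosome protein RUXF (AT4G30220, -0.33 ± 0.0748) and the plastid ribosomal protein GHS1 (AT3G27160, -0.28 ± 0.0565). The 27 tested abscisic acid genes had 2 higher and 0 lower members, with 3 and 0 adjusted over the list alone (median 0.26, camera adjusted p = 1.35e-05, or 0.425 with an estimated correlation). The synthesis enzyme NCED3 (AT3G14440, 1.08 ± 0.19) was higher. Against 73 calls there were 1 with the compared groups alone, 170 with a replicate block, 28 by edgeR and 191 by DESeq2. Left-out libraries gave 37, 0 and 10 without numbers 1, 2 and 3, 3 and 5 without Col local 2 min replicates 2 and 3, and 8 and 8 without myb30 local 2 min replicates 1 and 3.

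Local leaves at 8 min had 0 higher and 3 lower genes in myb30, which were AT2G06995 (-3.16 ± 0.54, adjusted p = 0.0217), VIM3 (-0.87 ± 0.16) and the plastid gene emb2184 (AT1G75350, -0.25 ± 0.0485). By limma 1670 genes in either direction had an unadjusted p under 0.05, and edgeR and DESeq2 called 2 and 90 in all, with no adjusted p from DESeq2 for 15166 of the genes. The 3 called genes became 31 without the filter on low values. Dropping libraries gave 0, 0 and 25 without numbers 1, 2 and 3, 0 and 0 without Col local 8 min replicates 1 and 2, and 0, 1 and 0 without myb30 local 8 min replicates 1, 2 and 3.

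After 30 min in local leaves 50 genes were higher and 227 lower in myb30. Among the highest were AT1G75945 (2.74 ± 0.56, adjusted p = 0.00440), the flowering repressor MAF5 (AT5G65080, 1.55 ± 0.37), WRKY26 (AT5G07100, 1.47 ± 0.31), AT3G51230 (1.06 ± 0.23), AT2G15042 (0.92 ± 0.23), AT5G18360 (0.90 ± 0.22) and AT5G02640 (0.88 ± 0.24). The lowest were AT2G06995 (-2.41 ± 0.54, adjusted p = 0.0104), AT3G05955 (-1.86 ± 0.43), AT1G47370 (-1.42 ± 0.38), the amino acid transporter AT5G02170 (-1.36 ± 0.34), the peptide transporter PTR5 (AT5G01180, -1.28 ± 0.19), the small nucleolar RNA AT4G39361 (-1.08 ± 0.27) and HSP18.2 (AT5G59720, -1.06 ± 0.21). The 27 tested heat shock proteins and factors had 0 higher and 4 lower members, with 0 and 9 adjusted over the list alone (median -0.75, camera adjusted p = 4.32e-12, or 0.0784 with an estimated correlation). HSP70B (-1.01 ± 0.18), HSP15.7 (-0.99 ± 0.23) and BAG6 (-0.81 ± 0.21) were lower in myb30. AT5G02170 (-0.72) did not pass without myb30 replicate 3. The share of higher genes among the calls was 18.1%, against 30.3% after quantile normalization and 86.7% scaled to the same total, which moved the median of all genes by 0.13. Other settings moved the 277 genes to 1087 scaled to the same total and 0 with the compared groups alone. Fewer libraries gave 33 and 23 without numbers 1 and 3, 120 without Col local 30 min replicate 3, and 131 and 152 without myb30 local 30 min replicates 1 and 3.

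In systemic leaves before high light limma called 0 genes, with 1587 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 1. The genes with the smallest p were AT2G23100 (0.66 ± 0.15, adjusted p = 0.454), AT5G11610 (0.74 ± 0.17, adjusted p = 0.454) and the trafficking factor GN (AT1G13980, 0.21 ± 0.0496, adjusted p = 0.454). With the exchange 9 genes were higher and 5 lower in myb30. Chosen after the values were seen, these held AT2G06995 (-2.84 ± 0.32), AT2G05914 (-2.22 ± 0.32) and AT3G05955 (-1.76 ± 0.31), lower, and AT1G75945 (2.52 ± 0.43) and MAF5 (1.69 ± 0.28), higher. Against 0 calls there were 10 without both libraries in doubt. Leaving out libraries gave 20 without number 3, and 4 without Col systemic 0 min replicate 2.

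At 2 min in systemic leaves 7 genes were higher and 8 lower in myb30. Higher were AT1G75945 (3.56 ± 0.56, adjusted p = 0.00394), MAF5 (2.09 ± 0.37), the ubiquitin ligase PUB19 (AT1G60190, 1.63 ± 0.33), the ERF factor AT1G22190 (1.04 ± 0.20) and the pectin precursor enzyme GAE1 (AT4G30440, 0.48 ± 0.10). Lower were AT2G06995 (-3.34 ± 0.54, adjusted p = 0.00394), AT3G05955 (-2.54 ± 0.43), the branched-chain ketoacid dehydrogenase subunit AT5G09300 (-1.30 ± 0.27), the RNA-binding protein GR-RBP2 (AT4G13850, -0.45 ± 0.0886), the NDH assembly factor CRR41 (AT1G51100, -0.45 ± 0.0816), RUXF (-0.41 ± 0.0748) and the plastid ribosome protein PSRP4 (AT2G38140, -0.35 ± 0.0729). Of the called genes 46.7% were higher, against 33.3% after quantile normalization. Other fits moved the 15 calls to 33 after quantile normalization, 9 scaled to the same total, 1 with the compared groups alone and 117 by DESeq2. Omitting libraries gave 0 and 5 without numbers 2 and 3, 2 without Col systemic 2 min replicate 2, and 27 and 4 without myb30 systemic 2 min replicates 1 and 3.

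At 8 min 1 gene was higher and 1 lower in systemic myb30 leaves, the lower being AT2G06995 (-3.17 ± 0.54, adjusted p = 0.0200). The higher one, chosen after its values were seen, was the membrane protein gene TSPO (AT2G47770, 2.24, adjusted p = 0.0278), at 20.6 ± 7.08 against 3.79 ± 2.53. Higher genes made up 50% of the calls, against 28.6% after quantile normalization. The 2 called genes became 1 with a pseudocount of 8, 7 after quantile normalization, 7 with a replicate block, 1 by edgeR and 16 by DESeq2. Left-out libraries gave 0, 0 and 4 without numbers 1, 2 and 3, 0, 0 and 1 without Col systemic 8 min replicates 1, 2 and 3, and 1 and 0 without myb30 systemic 8 min replicates 2 and 3.

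Systemic leaves at 30 min had 100 higher and 42 lower genes in myb30. The highest were the glycerophosphodiesterase SRG3 (3.1 ± 0.59, adjusted p = 0.00396), the phosphate sensor protein SPX1 (AT5G20150, 2.86 ± 0.40), at 6199.9 ± 1547 against 873 ± 305 in Col, AT1G75945 (2.82 ± 0.56), AT5G20790 (2.65 ± 0.48), the purple acid phosphatase PAP17 (AT3G17790, 2.26 ± 0.48), MAF5 (1.64 ± 0.37) and MYB13 (1.63 ± 0.37). The lowest were AT2G06995 (-3.31 ± 0.54, adjusted p = 0.000679), AT3G05955 (-2.13 ± 0.43), AT2G05914 (-1.99 ± 0.49), AT4G16745 (-1.13 ± 0.15), the sugar-starvation gene AT3G15450 (-1.11 ± 0.24), the RING protein AT1G26800 (-1.05 ± 0.26) and the zinc finger gene AT5G22920 (-1.02 ± 0.22). The 9 tested dark and sugar-starvation genes had 0 higher and 3 lower members, with 0 and 9 adjusted over the list alone (median -0.63, camera adjusted p = 1.70e-13, or 0.00760 with an estimated correlation). TPS11 (-0.73 ± 0.16), AT1G60140 (-0.36 ± 0.0863) and TPS8 (-0.62 ± 0.15) were lower in myb30. AT1G26800 (-0.67) and AT5G22920 (-0.66) did not pass without myb30 replicate 1. The share of higher genes among the calls was 70.4%, against 87.4% scaled to the same total. Other settings moved the 142 genes to 3 with the compared groups alone and 238 by DESeq2. Dropping libraries gave 15, 87 and 13 without numbers 1, 2 and 3, 51 and 69 without Col systemic 30 min replicates 2 and 3, and 50, 357 and 24 without myb30 systemic 30 min replicates 1, 2 and 3.

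Whether the response differed between genotypes was tested as an interaction, the change in myb30 minus that in Col. At 2 min in local leaves limma called 0 genes, with 842 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 56. The smallest p were those of AT1G50745 (5.57 ± 1.01, adjusted p = 0.0667), the ethylene synthesis gene ACS6 (AT4G11280, 3.08 ± 0.64) and NUDT4 (AT1G18300, 2.83 ± 0.62). Against 0 calls there were 1 without the 3 outlying libraries. Fewer libraries gave 8 without number 1, 5 and 1 without Col local 0 min replicates 1 and 2, 21 without Col local 2 min replicate 1, 1 and 1 without myb30 local 0 min replicates 2 and 3, and 1 without myb30 local 2 min replicate 2. At 8 min limma called 0 genes, with 646 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 0, with HDA08 (AT1G08460, -0.62 ± 0.14, adjusted p = 1.000), AT2G27630 (2.33 ± 0.58) and the NDH subunit PnsB5 (AT5G43750, -0.24 ± 0.0614) at the smallest p.

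At 30 min in local leaves the change in myb30 was higher than in Col for 5 genes and lower for 49. It was higher for MAKR3 (AT2G37380, 1.58 ± 0.29, adjusted p = 0.00547), the subtilase AT5G03620 (0.97 ± 0.22) and AT1G58590 (0.77 ± 0.17), and lower for the peptide transporter PTR5 (-1.16 ± 0.27, adjusted p = 0.0467), the PILS-type auxin carrier AT5G01990 (-1.14 ± 0.23) and the splicing factor AT2G30000 (-1.04 ± 0.15). Also higher, and chosen after their values were seen, were AT1G36060 (3.5, adjusted p = 0.048), with levels under the minimum for named genes, and the phospholipase PLDEPSILON (AT1G55180, 0.58, adjusted p = 0.0467). Of the called genes 9.26% were higher, against 70.6% scaled to the same total, which moved the median of all genes by 0.17. Other fits moved the 54 calls to 17 after quantile normalization, 34 scaled to the same total, 0 with the compared groups alone, 95 by DESeq2 and 19 without the 3 outlying libraries. Leaving out libraries gave 0 and 0 without numbers 1 and 3, 22 without Col local 0 min replicate 3, 19 without Col local 30 min replicate 3, 34 without myb30 local 0 min replicate 2, and 19, 119 and 23 without myb30 local 30 min replicates 1, 2 and 3.

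The same interaction in systemic leaves gave no calls by limma at 2 and 8 min. At 2 min limma called 0 genes, with 1886 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 0, and the smallest p were those of AT5G18180 (2.21 ± 0.46, adjusted p = 0.399), CIPK20 (AT5G45820, -0.76 ± 0.16) and AT1G18340 (-0.48 ± 0.11). The exchange gave 18 higher and 0 lower genes. The higher ones included, chosen after their values were seen, WRKY40 (6.85 ± 1.46), ACS6 (3.15 ± 0.60) and CYP707A3 (4.87 ± 0.96). The exchange puts the 0 min library with WRKY40 at 3317 into Col, and by limma no gene passed without both libraries in doubt or without the 3 outlying ones. Omitting libraries gave 1 without Col systemic 2 min replicate 1. At 8 min limma called 0 genes, with 2335 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 42, with AT1G12790 (-0.76 ± 0.15, adjusted p = 0.0844), DJ1A (AT3G14990, 1.05 ± 0.20) and the Aurora kinase AUR2 (AT2G25880, 1.07 ± 0.22) at the smallest p. After the exchange limma called 0 genes, with 1709 at an unadjusted p under 0.05 (edgeR and DESeq2 were not run). Left-out libraries gave 3 and 51 without Col systemic 0 min replicates 1 and 2, and 1 without myb30 systemic 8 min replicate 1.

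At 30 min in systemic leaves the change in myb30 was higher for 20 genes and lower for 8. It was higher for SPX1 (2.62 ± 0.57, adjusted p = 0.0429), BBX32 (1.61 ± 0.35) and BBX31 (1.44 ± 0.30), and lower for the zinc finger gene AT5G44260 (-1.67 ± 0.34), AT5G65207 (-1.29 ± 0.27) and AT4G16745 (-1.25 ± 0.22, adjusted p = 0.0109). SPX1 went from 2175 ± 1429.8 to 6199.9 ± 1547 in myb30 and from 1709 ± 674 to 873 ± 305 in Col. The 9 tested dark and sugar-starvation genes had 0 higher and 1 lower members, with 0 and 8 adjusted over the list alone (median -0.75, camera adjusted p = 2.93e-09, or 0.0518 with an estimated correlation). TPS11 had a lower change in myb30 (-1.04 ± 0.23). Exchanged libraries gave 30 higher and 8 lower genes, and BBX31, AT5G44260, AT5G65207, AT4G16745 and TPS11 no longer passed. Against 28 calls there were 16 without the filter on low values, 16 scaled to the same total, 0 with the compared groups alone, 117 by DESeq2 and 17 without both libraries in doubt. Dropping libraries gave 0, 4 and 0 without numbers 1, 2 and 3, 15 and 16 without Col systemic 0 min replicates 1 and 2, 18, 12 and 2 without Col systemic 30 min replicates 1, 2 and 3, 12 and 3 without myb30 systemic 0 min replicates 1 and 2, and 2, 194 and 4 without myb30 systemic 30 min replicates 1, 2 and 3.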

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

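Tests chosen only after their result was seen were those of the library genotypes, the fits with libraries exchanged or both left out and the reading of splits by the labels of the later time. With the libraries in doubt, Col and myb30 systemic 0 min replicate 3, an exchange between the genotypes is a candidate explanation. A first set of 32 genes at least 2-fold apart decided nothing, since 53.1% and 50% lay nearer the other genotype where libraries not in doubt reached 62.5%. Of the 8 genes that part all libraries outside systemic 0 min, chosen after that, 100% did so in both. Their median position, from 0 at the own to 1 at the other genotype, was 0.986 and 1.08, which a mixture of both would hold well under 1, and at most 12.5% did so in the other libraries with high WRKY40, against stress transcripts as the source. Correlation with the local 0 min library of the same number went from 0.143 to 0.368 in Col and from 0.150 to 0.332 in myb30 on exchange, and where such an exchange took place was not tested.

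By limma, edgeR and DESeq2 no gene was called in myb30 systemic leaves at 2 min. Neither the outlying 0 min library nor the exchange was the whole cause, since 55 genes were called without that library (2315 in Col) and 63 with the exchange (1309 in Col). A smaller change in the mutant stays open. Over the 2086 genes called in Col local leaves at 2 min, the median change in myb30 systemic leaves was 0.331 of that in Col, 0.144 without myb30 systemic 2 min replicate 1 and 0.211 without myb30 systemic 0 min replicate 3. With the exchange it was 0.411, from 0.213 to 0.517 without any 1 library (lowest without myb30 systemic 2 min replicate 1, then 0.220 without Col systemic 0 min replicate 3), but over the 325 genes called in myb30 local leaves it was 1.45 (1.05 to 1.76 without any 1 library, and 3.59 with the exchange). A bound of 0.8 there, set beforehand to speak against a smaller change, was wrong: local and systemic libraries of a number deviate together, so each choice can raise the change of its own genotype, and neither ratio decides. A shift of the mutant at 0 min, 0.279 of the Col change (0.220 to 0.392 without any 1 library, and 0.215, 0.117 to 0.371, with the exchange), rests on the same genes and stays open, as does a biological difference.

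Clock genes differed at 2 min in Col systemic leaves, with LHY lower (-1.33, and -1.28 with the exchange). A later time of day at harvest is a candidate explanation. The median of 9 tested dawn genes, which fall through the morning, was -0.29 (-0.38 to -0.24 without any 1 library, and -0.40 with the exchange). In myb30 at 2 min it was -0.0727 in systemic and -0.18 in local leaves, where limma called 0 of them. Time of harvest stays open, as times are separate harvests. High light acting on the lit leaf was predicted to lower dawn genes further in local leaves. At 30 min, however, 4 rose and 4 fell in Col local leaves (median 0.35), against 0 and 5 in systemic leaves (median -0.56). High light thus need not lower these genes, and the prediction cannot decide. At 2 min their local minus systemic median in Col was 0.15 (0.0840 with the exchange), without a further fall in lit leaves. It was 0.0604 to 0.26 without any 1 library. A signal from lit to unlit leaves was not tested.

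Local and systemic changes in Col differed for 8 genes at 2 min (AT1G01310 4.74, PMEI1 3.96, AT1G59860 3.46 and LTL1 -3.42), 811 at 8 min (AT1G71000 11.97, HSP17.6A 11.57, HSP23.6 11.17, PDF1 -5.28, LTL1 -3.80 and AT1G06080 -3.58) and 7206 at 30 min (HSP22.0 15.35, HSP23.6 14.56, AT1G71000 14.45, PDF1 -5.63, ATCTH -5.25, AT3G15450 -5.14 and MYB30 -1.60), with those of AT1G71000, HSP23.6 and HSP22.0 set by the pseudocount of 1, as groups lay near 0, and no measure of size. Genotype changes at 30 min differed for 54 genes in local leaves (MAKR3 1.58, AT5G03620 0.97, AT1G58590 0.77, PTR5 -1.16, AT5G01990 -1.14 and AT2G30000 -1.04) and 28 in systemic leaves (SPX1 2.62, BBX32 1.61 and, not passing with the exchange, BBX31 1.44, AT5G44260 -1.67, AT5G65207 -1.29 and AT4G16745 -1.25). AT4G16745 is 1 of the 8 genes that part the genotypes, so exchanged labels could give its value. Of 100 splits of the same libraries, 4 and 8 between genotypes in local and systemic leaves called as many genes (highest others 128 and 1043). Between leaves 8, 6 and 7 did at 2, 8 and 30 min (505, 1586 and 8056), the real one included. Of these splits, 3, 5, 6, 6 and 7 kept the true labels of the later time and its group difference, so the shares do not decide. Between leaves at 8 and 30 min the 89 splits with other labels then called at most 24 and 17 genes. These put that time's leaf difference into the spread and cannot decide. Heat shock genes held there with an estimated correlation, against chance. It stays open otherwise, and the other comparisons' counts fall to 0 with the compared groups alone. A count of 0 (limma), as in the other genotype interactions, is met by all 100 splits and decides nothing. Highest others were 47 and 0 in local and 452 and 832 in systemic leaves at 2 and 8 min.

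Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. Real count and highest other were 2086 and 1, 5079 and 0 and 10507 and 1 in Col local leaves at 2, 8 and 30 min, 2315 and 3, 4385 and 0 and 6787 and 4 in Col systemic leaves, 325 and 14, 3661 and 57 and 8616 and 1 in myb30 local leaves and 0 and 32, 172 and 4 and 2273 and 8 in myb30 systemic leaves. Between genotypes they were 2 and 0, 73 and 0, 3 and 52 and 277 and 2 in local and 0 and 337, 15 and 1, 2 and 0 and 142 and 0 in systemic leaves at 0, 2, 8 and 30 min. All 10 splits met counts of 0, as they must. Between genotypes in local leaves at 8 min 2 met the count, elsewhere the real one alone. Splits with 337, 832 and 1043 genes where real counts were 0, 0 and 28 point to a structure of the samples. Libraries of a number correlated between groups (mean 0.122, others -0.061), and a link was not tested.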

How the results depend on the processing

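Tests chosen only after the result was seen were the fits with the exchange, without both libraries in doubt and without the 3 outlying 0 min libraries. Counts of called genes beyond 1.5 times the reported one follow (genotype stands for myb30 against Col), and the cause was not tested except where fewer libraries were fitted. The compared groups fitted alone gave Col local 2 min (620) and 8 min (2910), Col systemic 2 min (634) and 8 min (1859), myb30 local 2 min (151) and 8 min (1867), myb30 systemic 8 min (3) and 30 min (692), genotype local 0 min (0), 2 min (1) and 30 min (0), genotype systemic 2 min (1) and 30 min (3), genotype by time local 30 min (0), genotype by time systemic 30 min (0), leaf by time 2 min (0) and 8 min (439). DESeq2 gave myb30 local 2 min (561), myb30 systemic 8 min (267), genotype local 0 min (10), 2 min (191) and 8 min (90), genotype systemic 0 min (1), 2 min (117), 8 min (16) and 30 min (238), genotype by time local 2 min (56) and 30 min (95), genotype by time systemic 8 min (42) and 30 min (117). Counts by edgeR were myb30 systemic 8 min (94), genotype local 0 min (1) and 2 min (28), genotype systemic 8 min (1). A block for the library number gave myb30 local 2 min (569), myb30 systemic 8 min (400), genotype local 2 min (170) and 8 min (49), genotype systemic 2 min (130), 8 min (7) and 30 min (249), genotype by time local 30 min (82), genotype by time systemic 8 min (11) and 30 min (66). A block by pool of plants gave leaf by time 8 min (1655). Quantile normalization gave genotype systemic 2 min (33) and 8 min (7), genotype by time local 30 min (17). Scaling to the same total gave genotype local 30 min (1087), genotype systemic 2 min (9), genotype by time local 30 min (34), genotype by time systemic 30 min (16), leaf by time 8 min (1305). Without the filter on low values there were genotype local 8 min (31), genotype by time systemic 30 min (16). A pseudocount of 8 gave genotype local 0 min (1), genotype systemic 8 min (1). Without the 3 outlying 0 min libraries there were Col local 2 min (946), myb30 systemic 2 min (81), 8 min (267) and 30 min (1401), genotype local 0 min (6), genotype by time local 2 min (1) and 30 min (19), leaf by time 8 min (487). The exchange gave Col systemic 2 min (1309), myb30 systemic 2 min (63) and 8 min (457), genotype systemic 0 min (14), genotype by time systemic 2 min (18). Without both libraries in doubt there were Col systemic 2 min (1128), myb30 systemic 2 min (52), 8 min (259) and 30 min (1450), genotype systemic 0 min (10), genotype by time systemic 30 min (17). With any 1 library or number left out, the lowest and highest counts were Col local 2 min (73 to 2112) and 8 min (2066 to 4843), Col systemic 2 min (269 to 2455) and 8 min (1542 to 4059), myb30 local 2 min (38 to 515) and 8 min (1738 to 3947), myb30 systemic 2 min (0 to 55), 8 min (1 to 297) and 30 min (597 to 2163), genotype local 0 min (0 to 4), 2 min (0 to 105), 8 min (0 to 25) and 30 min (23 to 354), genotype systemic 0 min (0 to 20), 2 min (0 to 27), 8 min (0 to 4) and 30 min (13 to 357), genotype by time local 2 min (0 to 21) and 30 min (0 to 119), genotype by time systemic 2 min (0 to 1), 8 min (0 to 51) and 30 min (0 to 194), leaf by time 2 min (0 to 16) and 8 min (307 to 946).

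At an adjusted p under 0.01 the local and systemic Col leaves shared 261, 847 and 1841 calls at 2, 8 and 30 min. Col and myb30 shared 20 and 1397 in local leaves at 2 and 8 min and 39 and 926 in systemic leaves at 8 and 30 min. The MYB30 genotype ratio in systemic leaves at 0 min changed sign with the exchange (-0.38) and in each fit without Col systemic 0 min replicate 3 (-0.12 to -0.0379). It ranged from -0.12 to 0.51 with libraries left out. At 8 min it passed by DESeq2 (-0.91), where the cause was not tested. Where numbers paired libraries, the block moved no other count beyond 1.5 times, and in 4 of 20 comparisons each correlated best with its own number. Of 225 list calls, 11 held with an estimated correlation, 222 with the block and 199 after quantile normalization, which turned 2. Among the values of named genes, those that kept their sign and side of the threshold were 270 with a pseudocount of 0.5 and 264 with 8, 266 with the block, 257 by DESeq2, 251 after quantile normalization, 251 scaled to the same total, 247 without the filter, 246 by edgeR and 162 with the compared groups alone, and 108 no longer passed in this last fit. With 1 library or number left out, 1933 kept both and 770 no longer passed. Where a number was left out, the lone or paired libraries are assumed to vary like the other groups. With at least 70514715 reads per library, depth limits the genes near 0 listed above as levels, and elsewhere the spread between 3 libraries sets the precision.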

Other observations

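Tests chosen only after the result was seen were the direct comparisons of local with systemic leaves, the test of decay and the medians with SDD1 and TMM and at 0 min. By limma 0, 26, 2030 and 9858 genes differed between Col local and systemic leaves at 0, 2, 8 and 30 min, and 0, 8, 765 and 8205 in myb30, with 842 and 1094 at 0 min at an unadjusted p under 0.05, where edgeR and DESeq2 were not run. A replicate block by pool of plants gave 78 and 3475 in Col at 2 and 8 min and 1398 in myb30 at 8 min, where the numbers paired the leaves, and the exchange gave 0 and 0 at 0 min. Without the block, at 2 min 14 were higher and 12 lower in Col local leaves. Among the lower were the stomatal lineage genes SDD1 (AT1G04110, -2.59) and TMM (AT1G80080, -1.54), the guard cell kinase HT1 (AT1G62400, -0.73), the expansin EXPA16 (AT3G55500, -1.61), and PDF1 (-3.70). The higher included HSP15.7 (1.32), AT1G59860 (3.32) and the mitochondrial import gene TIM23-3 (AT3G04800, 1.68).

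The 12 lower genes could reflect leaves of another age or position at harvest. Over 11 tested genes of young leaves and the stomatal lineage, the median difference of local and systemic changes was -0.0445 (-0.12 to -0.00459 without any 1 library). This list lacks SDD1 and TMM, and with both it was -0.0973 (-0.22 to -0.00821 without any 1 library). Before high light the 12 genes had a median local minus systemic difference of -0.0549 in Col (-0.30 to 0.0559 without any 1 library, -0.31 with the exchange) and -0.61 in myb30 (-0.90 to -0.44 without any 1 library, -0.58 with the exchange, PDF1 -2.23, LTL1 -1.99). This stays open. Steady decay in high light would need half-lives of 0.476 to 4.33 min and, at that rate, a median further local change of -5.96 by 30 min. The one measured was -0.0974 and that of the local to systemic difference -0.40 (-0.55 to -0.32 without any 1 library). Both argue against steady decay. A fall to a new level by 2 min needs half-lives at most as long and was not tested.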
